A study of Mus musculus with 6 samples.

How the data were processed

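The series holds 6 poly(A)-selected RNA-seq libraries of LPS-treated RAW264.7 cells, 3 with LPS alone and 3 with LPS and BMSC co-culture. Groups and replicate numbers were taken from the sample titles, which call the replicates biological. The title of LPS replicate 3 gives the cell line as RAW264.9, while its cell line tag says RAW264.7, and it was kept in its group. Per the labels' protocols, RNA was extracted with Trizol, mRNA was captured on oligo(dT) beads and fragmented, cDNA was primed with random hexamers, and fragments of about 350 bp were amplified by PCR. The protocol names no step that marks strand.

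The authors deposited 1 table with read counts and FPKM for each library. Per the submitters' processing notes, HISAT2 2.0.5 and the build mm10 were used; the counting tool, the gene annotation and any strand setting are not given in the sources used here. The deposited counts are whole numbers per gene, not normalized. The deposited FPKM values equal the count divided by the table's gene length and by the column's total count, to within 3 to 12 reads in that total. The table has 21958 gene rows with values. In addition, 1 row holds no values and was not analysed here. Of the rows, 21850 have an Ensembl identifier that is in GENCODE M21 (GRCm38), 21722 of them protein coding. The table's start position equals the GENCODE M21 start for only 517 genes, whereas the start-to-end span is equal for 21393. The table's coordinates thus mostly differ from GRCm38, the build that mm10 names; no other build was compared. Positions printed here come from GENCODE M21 by identifier and are GRCm38; none were taken from the table. GC content is that of the longest M21 transcript, and gene length is the table's. For the 21 symbols on more than 1 row, the row with the highest total count kept the symbol and the others were named by their Ensembl identifier. The 51 rows without a symbol were also named by their identifier. Where strand was not used in counting, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies (such as the Sprr2, Stfa and Ifit families) are uncertain.

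Depth ranged from 17716460 to 22539884 counts per library, so 3 counts in a library, the floor taken for detection, are 0.133 to 0.169 CPM. Reads carry no molecular identifiers, so floors and counting intervals cover counting error only. Replicates of each group were compared by a chi-square test of their counts over genes with at least 20 counts in the pair, and every pair differed by more than sampling noise, so none was treated as a duplicate.

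The main test was edgeR 4.0.16 (R 4.3.3), quasi-likelihood with robust estimation, on the deposited counts, with TMM scaling, the tool's default expression filter by group (11103 genes kept) and group as the only term. Genes were called at a Benjamini-Hochberg adjusted p of 0.05. The biological coefficient of variation was 7.05%. Standard errors are on the log2 scale. The values per library are TMM-scaled CPM. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, for lists with at least 5 tested members, adjusted over 32 of 35 lists. Camera with an estimated correlation, and fry, were run beside it. No list passed camera with an estimated correlation, where the lowest adjusted p was 0.262 and 5 lists had an unadjusted p below 0.05; fry, which tests whether genes of a set move on balance in a direction and compares it with no other genes, passed 29. Counts of members higher or lower use the adjustment over all genes, and the adjustment over the list alone changed them in 7 lists, by at most 3 members.

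The 35 lists, the tests, the rule for named genes and the alternative settings listed below were fixed before the data were examined, the lists from textbook knowledge of macrophages, LPS responses, stromal cells and RNA quality. Named genes were 11 inflammation and repair genes, the 6 largest rises and the 6 largest falls among called protein-coding genes with a mean log2 CPM of at least 3 over the 6 libraries and no overlap between groups, up to 4 members per list by smallest p, and the 2 most abundant members of lists for other cell types and RNA quality. Genes without a proper symbol were left out of the largest changes. Any other gene is said to be chosen after its values were seen. Values of a few genes that the rule names are not reported here.

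These settings were RLE size factors, library totals only, DESeq2 1.42.0, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, no expression filter, at least 10 counts in every library, a replicate block, leaving out each library in turn and protein-coding genes only. An offset for gene length and GC content was added after seeing the data. It fits natural splines with 5 degrees of freedom for each property in each library. Gene Ontology terms in the deposited table were tested with camera, also after seeing the data. Figures were drawn with matplotlib 3.10.9.

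The scripts were tested on simulated counts with the means and library sizes of these libraries for co-culture against LPS alone. Over 11038 genes, edgeR recovered 84.8% of simulated 1.5-fold and 96.9% of simulated 2-fold changes and called 0.05% of unchanged genes. With a simulated length and GC trend (11042 genes), 63.78% of unchanged genes were called without the offset and 0.11% with it. That trend was linear in GC content and log2 length and equal in all co-culture libraries, a form that the splines can fit. In the data the trend differed between co-culture libraries. The simulation changed few genes and used a common dispersion, whereas 75.5% of tested genes were called in the data. Camera with the preset correlation called 0 of 100 unshifted lists and found the shifted list. The simulated genes were drawn independently, so this could not test whether the preset correlation suits the data. There the estimated correlation was 0.785 for the ribosomal protein list.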

Results

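RNA was sequenced from RAW264.7 cells, a mouse macrophage-like line that makes inflammatory cytokines when it meets lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria. There were 2 groups of 3 libraries, described in the labels as biological replicates. The first group had LPS alone and the second had LPS and co-culture with BMSCs, the usual abbreviation for bone marrow stromal cells. The labels name no group without LPS, so each value below is a difference between co-culture and LPS alone and not a response to LPS. The design text names a scaffold carrying BMSCs and the growth factor bFGF, and asks whether the combination changes the inflammatory response of these cells. The sample labels name BMSC co-culture only, and give neither the species of the BMSCs nor whether the cells were in contact. Total gene counts were 17716460, 19739822 and 22539884 in the LPS libraries and 21964252, 20454137 and 19720727 in the co-culture libraries. A gene with 3 counts in a library, taken as the detection floor, stood at 0.133 to 0.169 CPM before scaling.

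With co-culture, a set of cytokine, surface and lipid genes was more than 10-fold higher, and interferon-induced genes were lower. Cd93, a cell surface glycoprotein of myeloid and endothelial cells, was 37.3-fold higher, at 88.35 ± 5.24 CPM in co-culture and 2.35 ± 0.245 CPM with LPS alone (mean ± SD, n = 3 each). Il33, an alarmin cytokine, was 17.4-fold higher (10.4 ± 0.367 against 181.7 ± 14.3 CPM) and S100a8, a calcium-binding protein abundant in myeloid cells, 17.0-fold higher (29.57 ± 2.87 against 501.6 ± 42.1 CPM). Dgat2, which makes triglycerides, rose 19.2-fold. Tnfrsf9, the costimulatory receptor 4-1BB, and Thbs1, the matrix protein thrombospondin 1, each rose 16.6-fold. The copper transporter Atp7a was 16.5-fold lower (55.2 ± 4.95 against 3.352 ± 1.3 CPM), and the interferon-induced Ifit2 was 15.5-fold lower (201.7 ± 12 against 13 ± 2.56 CPM). Ifi211, another interferon-induced gene, fell 7.06-fold. Sacm1l, a phosphoinositide phosphatase, fell 6.88-fold, Tasor2 6.72-fold and Dennd4c 6.2-fold. These 12 genes were the 6 largest rises and the 6 largest falls under the rule for named genes, and their adjusted p ranged from 1.3e-09 (Cd93 and Tnfrsf9) to 3.79e-06 (Dennd4c) in edgeR's quasi-likelihood test.

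In GRCm38 coordinates, Cd93 (ENSMUSG00000027435) lies on chromosome 2 from 148436640 to 148443563, Il33 (ENSMUSG00000024810) on chromosome 19 from 29925114 to 29960718 and S100a8 (ENSMUSG00000056054) on chromosome 3 from 90668978 to 90670035. Atp7a (ENSMUSG00000033792) lies on chromosome X from 106027276 to 106124926 and Ifit2 (ENSMUSG00000045932) on chromosome 19 from 34550694 to 34576419. All 5 are annotated there as protein-coding genes. Their counts are those the authors deposited per gene, and which parts of a gene were counted is not given in the sources used here. Ifit genes have close paralogs, so reads could be divided between copies and their single-gene values are less certain.

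Across the 11103 genes tested, 8382 (75.5%) passed an adjusted p of 0.05, 4160 of them higher and 4222 lower in co-culture. Of these, 923 were at least 2-fold higher and 1135 at least 2-fold lower. The split depended on scaling. The share of calls that were higher was 49.6% with TMM scaling, 38.3% with library totals only and 39.1% on FPKM, as the median log2 fold change of all tested genes moved from 0.001 with TMM to -0.177 with library totals. Changes below are relative to the TMM scale unless another scale is named. With library totals the median of every list was lower too, turning below 0 for macrophage identity (-0.087), complement (-0.141), osteoclast (-0.167), p53 (-0.101), MHC class II (-0.022) and stromal marker (-0.021) genes. Every library of a group lay on the same side of every library of the other for 80.2% of tested genes, against 10% by chance for 3 against 3. The first principal component of log2 CPM, with 90.5% of the variance, separated the groups. Replicates of the co-culture group differed more from each other (chi-square per degree of freedom 5.16 to 26.82 between pairs) than those of the LPS group (1.71 to 2.11).

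Cytokine genes rose together, while genes induced by interferon fell. Of 29 tested genes for cytokines and enzymes that LPS induces in macrophages, 26 rose, 2 fell and 1 did not pass (27 and 2 adjusted over the list alone), with a median log2 fold change of 1.00 and a camera adjusted p of 4.77e-07 (adjusted p = 0.262 with an estimated correlation). Lif, a cytokine of the IL-6 family, rose 13.6-fold (34.1 ± 0.925 against 462.5 ± 31.3 CPM), Il1b 5.0-fold (651.5 ± 10.5 against 3256 ± 192 CPM), Osm 5.1-fold and the prostaglandin E synthase Ptges 3.16-fold. Il6 rose 3.63-fold (106.6 ± 5.76 against 386.9 ± 41.3 CPM), with an adjusted p of 1.66e-07 in the edgeR test. Nos2, the inducible nitric oxide synthase, rose 1.38-fold. Tnf was 1.5-fold higher (log2 0.58, SE 0.06), but its log2 fold change was -0.04 once a trend of fold change with gene length and GC content was taken out. Ptgs2, the inducible cyclooxygenase, was 1.24-fold higher with an adjusted p of 0.0221. From a log2 fold change of 0.32, it lost its call with library totals (0.14, adjusted p 0.294) and on FPKM (0.12, adjusted p 0.378). It also lost it without LPS replicate 1 (0.30, adjusted p 0.0766), LPS replicate 2 (0.28, 0.0853), co-culture replicate 2 (0.31, 0.065) or co-culture replicate 3 (0.20, 0.0558). Ptgs2 kept its call without LPS replicate 3 or co-culture replicate 1. With the length and GC trend taken out, its log2 fold change grew to 0.735 (adjusted p 1.82e-06 in the edgeR test). Of 17 chemokine ligand genes tested, 15 rose and 1 fell, with a median of 1.23, or 0.76 with the length and GC trend removed (6.03e-05, adjusted p = 0.262 with an estimated correlation). Among them Ccl22, a ligand of CCR4, rose 7.47-fold, and the neutrophil attractants Cxcl3 and Cxcl2 rose 6.43-fold and 3.24-fold. Ccl3 rose 2.51-fold. Of 57 interferon-stimulated genes, 44 fell and 7 rose, with a median of -0.90 (4.77e-07, adjusted p = 0.262 with an estimated correlation). Ifit3b fell 4.58-fold, Ifit1 3.64-fold (209.8 ± 6.82 against 57.59 ± 4.75 CPM) and Ifi44l 2.58-fold. Of 41 genes of the TLR4 and NF-kB pathway and its feedback inhibitors, 25 rose and 9 fell, with a median of 0.45 (0.00398, adjusted p = 0.262 with an estimated correlation). Traf1 rose 4.25-fold, Nfkbie 3.55-fold, the phosphatase Dusp1 3.49-fold and the mRNA-decay factor Zfp36 2.12-fold; these 4 include inhibitors of the pathway.

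**Figure D1:**
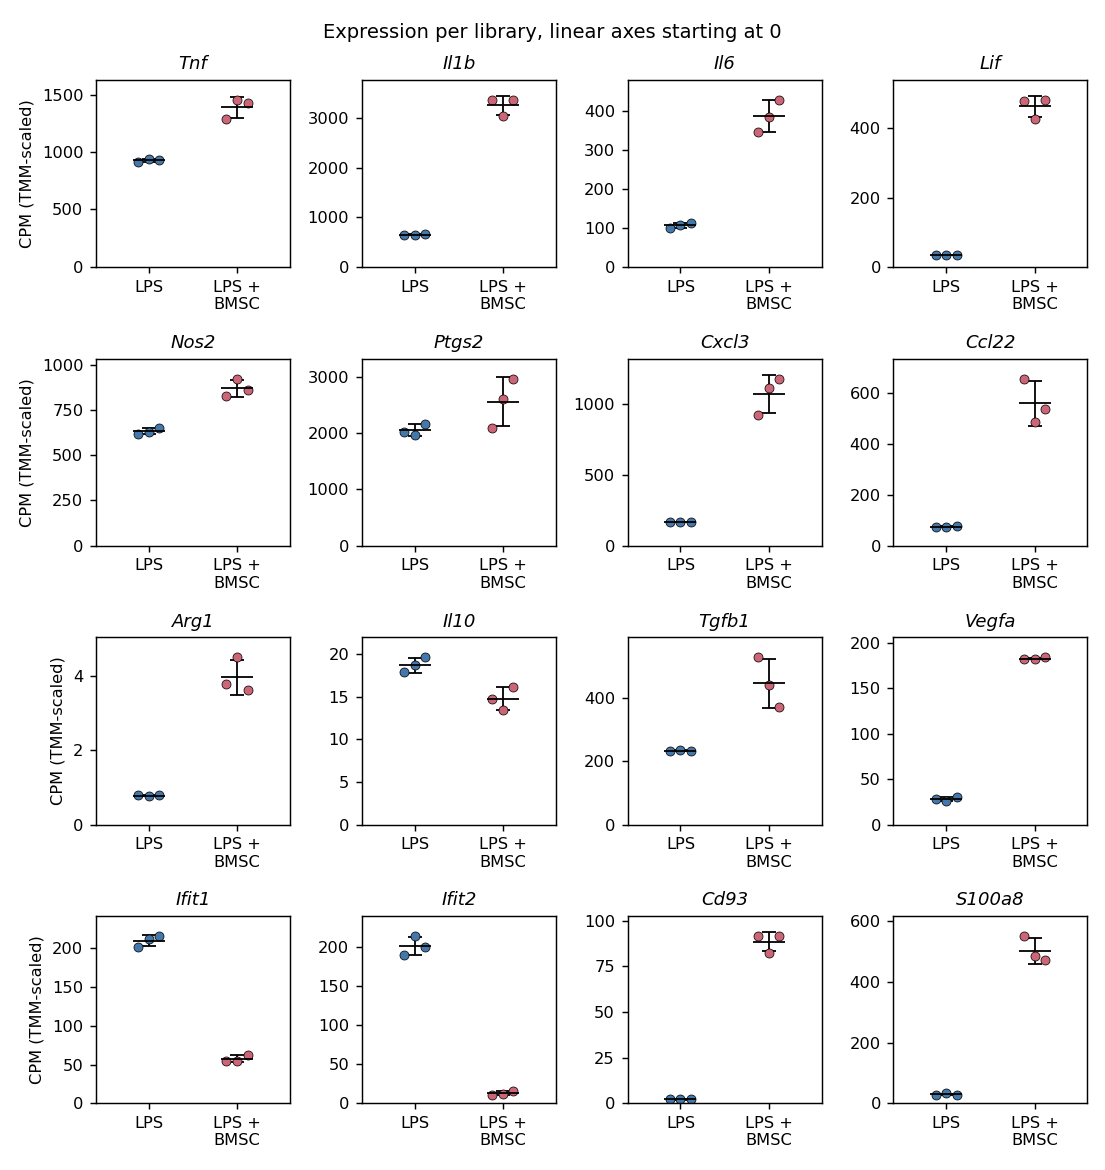
Each panel gives TMM-scaled CPM of 1 gene in the 6 libraries, as points, on a linear axis that starts at 0, with a horizontal bar at the group mean and error bars of 1 SD (n = 3 per group). Il1b stands near 651.5 CPM with LPS alone and 3256 CPM in co-culture, Ifit1 falls from 209.8 to 57.59 CPM, and the co-culture points of Ptgs2 spread widely around 2553 CPM.

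Genes linked to cAMP signalling and to alternative activation rose, with Vegfa in both lists. Of 33 cAMP, CREB and immediate-early response genes, 27 rose and 4 fell (28 and 4 adjusted over the list alone), with a median of 0.96 and a camera adjusted p of 1.29e-06 (adjusted p = 0.294 with an estimated correlation). Vegfa, the vascular endothelial growth factor, rose 6.52-fold (28.05 ± 1.84 against 183.0 ± 0.95 CPM), Ier3 3.73-fold, Dusp1 3.49-fold and Thbs1 16.6-fold. Of 19 genes of IL-4-type, M2-like activation, 12 rose and 4 fell, with a median of 0.63 and an adjusted p of 0.0307 (adjusted p = 0.363 with an estimated correlation). Besides Vegfa and Ccl22, this list was led by the transglutaminase Tgm2 (8.33-fold higher) and the chemokine Ccl17 (8.57-fold higher, 0.507 to 4.47 CPM, and 3.7-fold with the length and GC trend taken out); Vegfa and Ccl22 are also made by macrophages given LPS. Arg1, the arginase used as a marker of this state, rose 5.04-fold but stood at 3.97 ± 0.469 CPM in co-culture. Mrc1, the mannose receptor, had too few counts to be tested (0.113 ± 0.152 against 0.427 ± 0.171 CPM). Tgfb1 rose 1.91-fold, and Il10 fell by 0.34 on the log2 scale (SE 0.09, adjusted p 0.007). Surface markers of classical activation gave 10 higher and 2 lower of 16 (camera adjusted p 0.0622, or 0.0385 without co-culture replicate 1), and 10 and 5 with the length and GC trend removed. Cd86, at 3.89 CPM in co-culture, was 2.24-fold higher and Cd80 2.43-fold higher, whereas Fcgr1, an Fc receptor that interferon induces, was 1.72-fold lower. Secreted growth factors for bone, vessel and matrix cells gave 11 higher and 4 lower of 20 (0.0849, median 0.46, or 0.09 with the length and GC trend removed), with Angptl2 2.63-fold lower and Pdgfb 1.48-fold higher. Matrix proteases and their inhibitors gave 16 higher and 9 lower of 27 (0.0932, median 0.46, or 0.18 with the trend removed); Mmp9 rose 5.57-fold and Adam10 fell 2.19-fold.

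Metabolic and stress genes also shifted. Of 22 HIF target genes, 17 rose and 1 fell (median 0.75, camera adjusted p 6.03e-05, adjusted p = 0.294 with an estimated correlation). Ddit4, an inhibitor of mTORC1, rose 8.6-fold, the lipid droplet protein gene Hilpda 7.38-fold and the mitochondrial Higd1a 3.09-fold. Of 24 glycolysis genes, 16 rose and 3 fell (median 0.47, 0.00332, adjusted p = 0.294 with an estimated correlation). Those that rose included the lactate exporter Slc16a3 (2.89-fold), Pfkl (2.45-fold), Gapdh (2.15-fold) and Tpi1 (2.09-fold). Of 32 genes of the ATF4 and integrated stress response, 27 rose and 4 fell (median 0.70, 8.45e-06), with Trib3 at 6.57-fold, Ppp1r15a at 5.36-fold and Nupr1 at 4.51-fold (adjusted p = 0.363 with an estimated correlation). Of 23 ER chaperone and unfolded-protein genes, 16 rose and 5 fell (16 and 6 adjusted over the list alone), with a median of 0.34. That list passed with an adjusted p of 0.0284 but not without co-culture replicate 3 (0.0539), with the length and GC trend removed (0.102, 11 higher and 4 lower, median 0.12) or with an estimated correlation (adjusted p = 0.294). Herpud1 rose 2.55-fold, Manf 2.02-fold and Calr 1.68-fold. Of 57 nuclear-encoded respiratory chain genes, 50 rose and 3 fell (51 and 3 adjusted over the list alone). Their median was 0.83, with a camera adjusted p of 8.41e-09 and an adjusted p = 0.363 with an estimated correlation. With the length and GC trend removed, 35 were higher and 10 lower, with a median of 0.27. Cox4i1 rose 2.47-fold, Ndufs4 2.24-fold and Uqcrb 2.11-fold; Cox6b1 was 2.17-fold higher, a call that was lost with the length and GC trend taken out (log2 0.10). Lysosome and autophagy genes gave 25 higher and 8 lower of 40 (median 0.31, 0.027, adjusted p = 0.363 with an estimated correlation). The list did not pass with the length and GC trend removed (0.102, 22 higher and 11 lower, median 0.28). There the selective autophagy receptor Sqstm1 rose 2.0-fold and Cd63 2.03-fold, while Npc1 and Lipa, which free cholesterol from lysosomes, fell 2.8-fold and 2.34-fold.

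Lists of related lipid and redox genes did not pass as lists. Cholesterol synthesis and uptake gave 6 higher and 14 lower of 24 (6 and 15 adjusted over the list alone, camera adjusted p 0.128, median -0.33, or -0.16 with the length and GC trend removed), with Hsd17b7 2.05-fold and Stard4 1.71-fold lower. LXR and lipid handling gave 7 higher and 9 lower of 17 (0.607). The sterol exporter genes moved apart, Abca1 rising 2.71-fold and Abcg1 falling 2.57-fold, and the lipase Lpl fell 2.37-fold while the lipid droplet gene Plin2 rose 2.02-fold. NRF2 and antioxidant genes gave 17 higher and 8 lower of 28 (0.0811, median 0.39, or 0.19 with the trend removed), with Gpx4 2.31-fold, Prdx5 2.23-fold and Sod2 2.06-fold higher. Metallothionein, zinc and iron genes gave 7 higher and 6 lower of 15 (0.987), or 7 and 7 with the trend removed. Within that list the siderophore-binding Lcn2 rose 3.12-fold, and the iron exporter Slc40a1, the zinc exporter Slc30a1 and the transferrin receptor Tfrc fell 3.62-fold, 2.66-fold and 2.12-fold. Heat shock genes gave 9 higher and 4 lower of 16 (11 and 5 adjusted over the list alone, 0.274), with Hspe1 1.4-fold and Ahsa1 1.34-fold higher.

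Genes of the cell cycle were lower and those for ribosomal proteins higher. Of 39 S phase genes, 26 fell and 5 rose (median -0.43, or -0.23 with the length and GC trend removed, camera adjusted p 0.000888, adjusted p = 0.363 with an estimated correlation). The transcription factor E2f8 fell 2.81-fold, the DNA polymerase subunit Pola1 2.76-fold, Dtl 2.17-fold and the helicase Blm 2.08-fold. Of 46 genes of G2 and mitosis, 28 fell and 8 rose (29 and 8 adjusted over the list alone), with a median of -0.32, an adjusted p of 0.00986 and an adjusted p = 0.569 with an estimated correlation. It did not pass with the trend removed (0.0744, 9 higher and 24 lower, median -0.15). Nek2 fell 2.05-fold, Top2a 1.81-fold and Tmpo 1.74-fold, and Cks2 rose 2.24-fold. All 76 cytosolic ribosomal protein genes rose, with a median of 1.11 (0.58 with the trend removed) and an adjusted p of 3.26e-16 (adjusted p = 0.363 with an estimated correlation); Rps15a rose 2.18-fold, Rps13 2.17-fold and Rpl9 2.04-fold. These lists also differed between co-culture libraries. In replicates 1, 2 and 3 the median deviation from the co-culture mean, on the log2 scale, was 0.22, -0.05 and -0.16 for ribosomal protein genes, 0.16, -0.02 and -0.13 for respiratory chain genes, -0.10, 0.06 and 0.06 for S phase genes and -0.09, 0.07 and 0.05 for G2 and mitosis genes. Ribosomal protein genes have many processed pseudogenes, so single-gene values are less certain. The p53 target and apoptosis list gave 13 higher and 14 lower of 32 (0.788), or 14 and 9 with the length and GC trend removed, and a median of 0.08 that turned to -0.03, with the stress gene Gadd45a 11.4-fold, Gadd45b 2.36-fold and Cdkn1a 2.1-fold higher.

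Lists of macrophage surface, antigen presentation and osteoclast genes did not pass as lists. Macrophage identity genes gave 11 higher and 5 lower of 26 (camera adjusted p 0.273), or 9 higher and 8 lower with the length and GC trend removed, with a median of 0.09 that moved to 0.001. The LPS co-receptor Cd14 rose 1.84-fold, Clec4d 1.89-fold and the Fc receptor Fcgr3 2.12-fold, and the fractalkine receptor Cx3cr1 fell 2.41-fold. Complement and phagocytic receptor genes gave 8 higher and 8 lower of 22 (0.91), or 12 and 6 with the trend removed (median 0.04 to 0.13), with the integrin Itgax 2.64-fold lower and properdin, Cfp, 2.15-fold higher. Inflammasome genes gave 10 higher and 8 lower of 21 (0.547), or 10 and 4 with the trend removed, and their median turned from -0.05 to 0.11, with Txnip 2.36-fold higher, Il1a 2.11-fold higher and the interferon-induced Gbp5 4.85-fold lower. MHC class I genes gave 11 higher and 7 lower of 23 (0.452), or 8 higher and 11 lower with the trend removed, their median turning from 0.24 to -0.11, the transactivator Nlrc5 being 1.71-fold lower and H2-T24 2.14-fold lower. MHC class II genes gave 4 higher and 1 lower of 7 (0.249), or 2 higher and 4 lower with the trend removed, and their median turned from 0.16 to -0.27. The invariant chain gene Cd74 was 4.27-fold higher (121.1 ± 0.758 against 517.2 ± 110 CPM). Osteoclast genes gave 7 higher and 6 lower of 20 (0.924), or 6 and 7 with the trend removed (median 0.01 to -0.08); Mitf fell 2.49-fold and Atp6v0d2 2.86-fold, while Jdp2 rose 2.05-fold.

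Most markers of other cell types had few counts in co-culture. Of 42 markers of marrow stromal cells and fibroblasts in the table, 14 had no count in the co-culture libraries and 33 had at most 10 counts there in all. Of the 8 that could be tested, 2 rose and 2 fell (camera adjusted p 0.567), or 3 and 1 with the length and GC trend removed. The most abundant were S100a6 (2.66-fold higher, 382.6 CPM in co-culture) and Acta2 (1.8-fold higher, 18.26 CPM). Of 14 neutrophil and myeloid precursor markers, 4 could be tested, and 10 had at most 10 counts in co-culture. Of the 4, S100a8 and the antimicrobial peptide gene Camp rose, Camp 5.26-fold from 0.636 to 3.39 CPM, and Csf3r and Mmp8 fell 1.41-fold and 2.13-fold. The most abundant were S100a8 and Csf3r. None of 17 lymphoid and erythroid markers could be tested, the most abundant being Cd79a (0.307 CPM in co-culture) and Alas2 (0.118 CPM). Of 15 endothelial and adipocyte markers, 4 could be tested and 2 rose, Pecam1 2.97-fold to 3.65 CPM and Fabp4 1.76-fold to 84.94 CPM. Lists with fewer than 5 tested members had no camera test. As a sign of RNA quality, mitochondrially encoded genes took 2.85% to 2.96% of counts in the LPS libraries and 1.91% to 2.38% in the co-culture libraries. Of 11 such genes tested, 4 were higher and 2 lower (0.547), or 2 higher and 5 lower with the length and GC trend removed, where the median turned from 0.29 to -0.13. The most abundant of them, mt-Co1, fell 1.4-fold, and mt-Cytb was 1.01-fold higher (adjusted p 0.815), a sign that turned with library totals, on FPKM and with the length and GC trend removed. Reads shared with nuclear copies of the mitochondrial genome leave these values uncertain.

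Fold changes followed gene length and GC content across genes. The Spearman correlation of log2 fold change was -0.50 with gene length and 0.42 with GC content, over genes that are not independent replicates. The median log2 fold change was 0.58 in the set of 2221 tested genes with the shortest genes and -0.55 in the 2221 longest, and both properties together fitted 27.1% of its variance. Removing this trend from each library, a choice made after seeing the data, gave 7928 called genes. Of the 8382 genes called before, 6016 kept their call and direction, 548 were called in the opposite direction and 1818 were no longer called. Of the 15 lists past the threshold, 12 stayed past it in the same direction. The cytokine list kept a median of 0.95 (adjusted p 2.57e-05), chemokines 0.76 (0.00336), interferon-stimulated genes -0.65 (9.19e-10) and the integrated stress response 0.67 (2.17e-06). Members called higher and lower were then 21 and 4 of 29 for cytokines and 12 and 3 of 17 for chemokines. They were 4 and 48 of 57 for interferon-stimulated genes and 27 and 2 of 32 for the integrated stress response. The ribosomal protein list moved from a median of 1.11 to 0.58 with 65 of 76 still higher (3.96e-10), and respiratory chain genes from 0.83 to 0.27 (0.00811). The S phase list moved from -0.43 to -0.23 (0.000387). Not past the threshold without the trend were the G2 and mitosis list (0.0744), the ER chaperone list (0.102) and the lysosome list (0.102). Of the 12 genes with the largest rises and falls, all kept their direction, from 5.53 on the log2 scale for Cd93 to -3.68 for Ifit2. Of 141 tested named genes, 36 moved by more than 1.5 times. Among those that were higher, the log2 fold change became 3.39 for S100a8, 1.89 for Ccl17, 0.59 for Ccl3, 1.03 for Ier3, 2.09 for Hilpda, 2.39 for Ddit4, 2.09 for Trib3, 1.37 for Cd74 and 0.27 for Cd14. It became 0.52 for Cox4i1, 0.57 for Prdx5, 0.45 for Gpx4, 0.44 for Cks2, 0.49 for Gadd45b, 0.45 for Jdp2, 0.41 for Cfp, 0.70 for S100a6 and 1.31 for Camp, and grew to 1.75 for Sod2. Among those that were lower, it became -1.94 for Tasor2, -0.57 for Lpl, -0.78 for Pola1, -0.28 for Dtl, -0.24 for Top2a, -0.19 for Tmpo, -0.90 for Npc1 and -1.19 for Slc40a1.

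**Figure D2:**
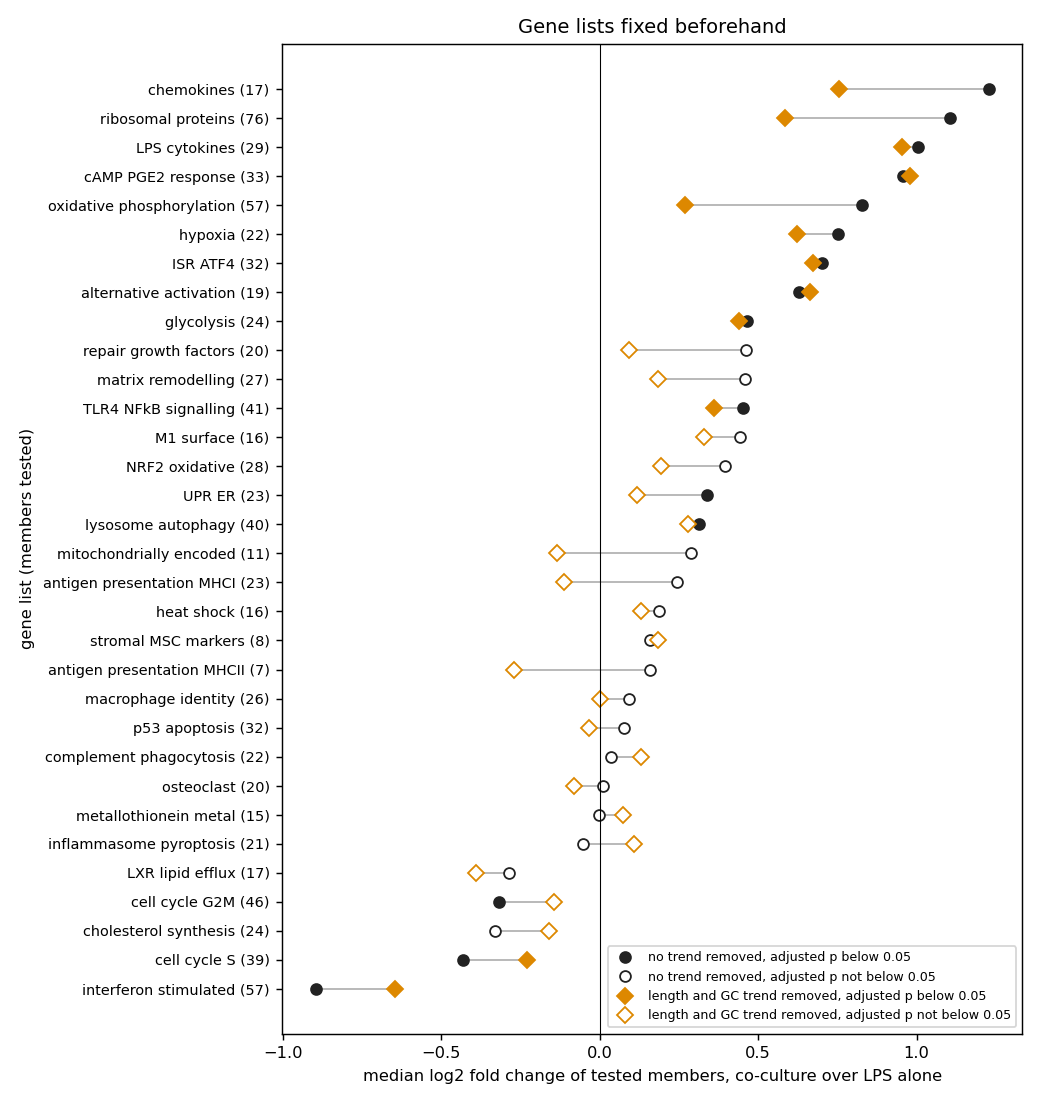
Each row is a gene list, with the number of members tested in parentheses, and its median log2 fold change of co-culture over LPS alone as circles; diamonds give the median with the length and GC trend removed, and filled symbols mark a camera adjusted p below 0.05. Cytokines stay near 1 (1.00 and 0.95) and interferon-stimulated genes stay lowest (-0.90 and -0.65), while ribosomal protein genes move from 1.11 to 0.58 and respiratory chain genes from 0.83 to 0.27.

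**Figure D3:**
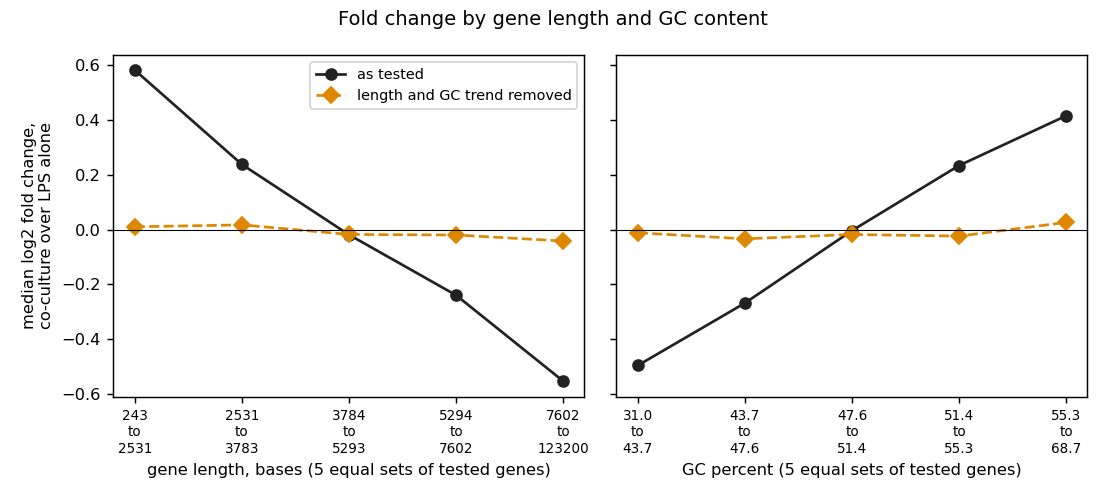
Median log2 fold change of co-culture over LPS alone in 5 equal sets of tested genes ordered by gene length in bases (left) and GC percent (right), as tested (circles) and with the trend of each library removed (diamonds). The medians run from 0.58 to -0.55 from short to long genes and from -0.50 to 0.42 from low to high GC content.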

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

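All settings here were chosen before the data were examined except the length and GC offset, added afterwards. Of 141 tested named genes, 136 kept direction and side of the threshold under each setting chosen beforehand that gave them a value (129 had a value under all 14 and 12 lacked at least 1), and 30 of 32 lists did so under RLE size factors, the replicate block and leaving out each library; the list exceptions, each from leaving out a co-culture library, are the M1 surface and ER chaperone lists, given with the results. Called genes numbered 8386 with RLE, 8406 with library totals, 8095 with DESeq2, 8509 without a filter, 8085 with at least 10 counts in every library, 8347 with protein-coding genes only and 7562 of 9463 on FPKM. Leaving out a library gave 7756 to 8576. Genes at least 2-fold higher, 923 in the main test, numbered 574 with library totals, 289 on FPKM and 635 with the length and GC offset. Library totals move the median of all genes by -0.177. On FPKM the tool, scaling and tested genes also differ, and 1 is added before the log, which shrinks folds of low values. In the simulation, 2-fold rises had a median log2 fold change of 0.886 on FPKM and 1.01 in edgeR. How much each difference contributes was not tested. Genes at least 2-fold lower, 1135 in the main test, numbered 1658 with library totals, 735 on FPKM and 605 with the length and GC offset. The offset removes the trend from short and long genes alike.

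The exceptions among genes were Ptgs2, Lgmn, Runx2, mt-Cytb and mt-Nd4. Signs turned for 5 named genes. With the length and GC offset, Tnf had a log2 fold change of -0.037, Ifi30 -0.194, Lgmn -0.272, mt-Cytb -0.237 and Chordc1 0.265. With library totals, Lgmn had -0.022 and mt-Cytb -0.165, and on FPKM the values were also -0.022 and -0.165. Beyond the shift of scale or trend that each setting makes, the cause was not tested. The metallothionein list, near 0 by camera (0.987), gave 0.00434 downward with fry. Runx2, at -0.478 in the main test, lost its call with DESeq2 (-0.478, adjusted p 0.0681), the offset (-0.197) and without LPS replicate 1 (-0.415), LPS replicate 2 (-0.44) or co-culture replicate 2 (-0.409).

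The replicate block gave 8217 called genes, and 8171 of the 8382 kept their call and direction. Same-numbered libraries did not deviate together (correlations of -0.042, -0.024 and 0.04). This does not decide whether the numbers pair the samples, as co-culture replicates 1 and 3 deviated with GC content (Spearman 0.488 and -0.533). At this depth, genes below 0.133 to 0.169 CPM, which is 3 counts in a library, could not be told from absent.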

Other observations

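The tests and gene choices here were made after the values were seen. Thinning the libraries to a common total decides nothing, as the totals of the groups overlap (correlation of fold change with length -0.497 before and -0.50 after). Genes annotated to protease inhibition were among those that rose. Among 1271 Gene Ontology terms with 15 to 200 tested genes, 5 passed camera both as tested and with the length and GC trend taken out, and none passed with an estimated correlation (lowest adjusted p 0.822, 20 terms at an unadjusted p below 0.05; 30 terms passed with the preset correlation before the trend was removed). Of 54 genes under negative regulation of endopeptidase activity, 34 rose, 7 fell and 13 did not pass (adjusted p 0.00179, 0.0122 without the trend, and adjusted p = 0.822 with an estimated correlation), and not all of them are inhibitors. Stfa3, a stefin that inhibits cysteine proteases, rose by a log2 fold change of 3.31 (47.82 to 472.6 CPM), Csta3 by 2.67 and the secreted leukocyte inhibitor Slpi by 2.17 (110.3 to 494.7 CPM), and by 2.44, 1.67 and 1.31 with the trend taken out; stefin genes have near-identical copies, so single values are uncertain. The other terms were cytoplasmic translation (80 of 82 higher), cellular response to interleukin-1 (31 higher and 6 lower of 45) and neutrophil chemotaxis (29 higher and 8 lower of 42), which share genes with the ribosomal and chemokine lists, and cellular response to interferon-beta (28 lower and 9 higher of 45).

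A few genes were close to absent with LPS alone. Il11, a cytokine of the IL-6 family, rose 165-fold (0.455 to 75.88 CPM, adjusted p 1.24e-08 in edgeR), the secreted protein gene Crispld2 144-fold (0.182 to 27.86 CPM) and the cornified envelope gene Sprr2d 117-fold (0.379 to 46.26 CPM, log2 6.86, or 5.82 with the length and GC trend taken out). Sprr2 genes are near-identical, so how their reads divide is uncertain. Crhbp, which binds corticotropin-releasing hormone, had 0 counts in the LPS libraries and 64, 50 and 39 in co-culture. Scaled by library totals and not by TMM, this is at least 16.4-fold higher against a floor of 3 counts per library. Gad1, which makes the transmitter GABA, had 1 count against 76 (73.4-fold, 95% exact counting interval 12.8 to 2940). Pdyn, the dynorphin precursor, had 1 against 63 (60.8-fold, 10.5 to 2440). The folds and intervals of Gad1 and Pdyn are also scaled by library totals, unlike the TMM-scaled folds of Il11, Crispld2 and Sprr2d.

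The trend with gene length and GC content was also present between co-culture replicates: the difference of co-culture replicates 1 and 3 followed the fold change measured on replicate 2 alone against the LPS mean (Spearman 0.66 across genes), as well as GC content (0.531) and length (-0.348), consistent with a library or RNA-quality trend that differs from library to library. Pairs of LPS libraries differed in total by 0.156 to 0.347 on the log2 scale, against 0.056 between the groups, yet their difference between the shortest and longest sets of genes was -0.052 (95% bootstrap interval over genes -0.058 to -0.046) to 0.038 times that between the groups, which argues against a difference in library size. A stronger response in replicate 1 in all gene groups alike would give the same correlation. It needs other lists to differ between replicates 1 and 3 as ribosomal protein genes do. Per unit of fold change, the interferon list differed 0.072 times as much (95% bootstrap interval over genes -0.249 to 0.279). The cytokine list differed 0.006 times as much (-0.447 to 0.45). Both intervals lie under 0.5, a bound set after the data were seen, and the cytokine interval ends close to it. These values lean against a response alike in all gene groups but do not exclude it. Without division by fold change, the cytokine list also differed 0.006 times as much (-0.308 to 0.395). That interval was too wide for the stricter bound set there, so that test could not tell. All these intervals treat the genes of a list as independent and may be too narrow. A length and GC trend would also be expected to move the cytokine list. Medians of fold change in matched genes averaged 0.314 for that list and 0.585 for ribosomal protein genes. Between replicates 1 and 3 its median difference was 0.002, against 0.378 for ribosomal protein genes. The cytokine list thus does not favour a library trend over a stronger response. Respiratory chain and cell cycle genes did differ between these replicates, so a stronger response of some gene groups only, in which the cytokine list (0.006) need not take part, cannot be told apart from a library trend. An effect of co-culture on short or GC-rich mRNAs also stays open, as does RNA integrity, which was measured per the labels but whose values were not used here.

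The rise of cytokine genes and fall of interferon-stimulated genes was set against the same trend as its whole cause. Lists of other genes matched on length, GC content and expression had a median as high as the cytokine list in 0 of 10000 draws (range -0.30 to 0.80 against 1.00). They had a median as low as the interferon list in 0 of 10000 draws (-0.35 to 0.41 against -0.90). The length and GC trend thus does not account for the whole of either, but may account for a part. Matched medians averaged 0.314 for the cytokine list, whose median was 0.95 with the trend removed. For the interferon list they averaged 0.066, opposite in sign to its fall, while its median moved to -0.65 with the trend removed. For ribosomal protein genes 0 of 10000 draws reached 1.11 (0.35 to 0.85), but the matched genes were less abundant (median log2 CPM 7.86 against 9.16), and the trend may account for a part, as the median fell to 0.58 without it. The matching used the table's gene length, which exceeds mRNA length for some of these genes. These draws therefore do not settle how much of their rise the trend accounts for. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 8382 genes in edgeR, and the highest of the others called 0 (14 to 34 genes at an unadjusted p below 0.05). Each of the others mixes both groups on each side, so the group difference adds to its spread and few calls follow in advance. No conclusion is drawn from the splits. Whether co-culture itself or another difference between the cultures, such as density, medium or time, changed these mRNAs was not tested.

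Several risen genes are also known from stromal cells or neutrophils, which could have been carried over. Mouse stromal cells as a source of Il11, Il33, Thbs1 and Crispld2 would bring fibrillar collagen and Sparc mRNA, yet the summed CPM of Col1a1, Col1a2, Col3a1 and Sparc was 5.16e-05 times that of the 4 genes, from 1 count in the co-culture libraries. Neutrophils as a source of S100a8 would bring S100a9, which had 6 counts against 29321 for S100a8, a ratio of 0.000205, and Ly6g had 0, although Camp rose from 41 to 199 counts in all. Both ratios argue against carried-over cells. Stromal cells of another species, whose reads align less well to mouse genes, were not tested.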
